A study of Mus musculus with 97 samples.

How the data were processed

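RNA was measured in 18 libraries of a mouse Sox2-AID ES cell line, 3 in each of 6 groups: early G1, late G1 and G2, each with and without auxin. Per the labels, cells were sorted on Hoechst and GFP levels, mitotic cells for ChIP-seq and MNase-seq were obtained with nocodazole at 50 ng/ml for 4 to 5 h and shake-off (the labels name no such step for ATAC-seq), and the MNase concentrations were 0.5, 16 and 128 with no unit. What GFP reports is not stated in the labels and is not assumed here. Groups and replicate numbers were taken from the sample titles. The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined.

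The deposited count table holds expected counts, which the values show to be estimated reads per gene rounded to whole numbers. The submitters' processing notes name STAR, RSEM, Bowtie2, MACS2 and the mm9 assembly, without versions or roles. A second deposited table holds TPM, made by the authors to 2 decimals. The third holds the authors' profile values around genomic sites for ATAC-seq, MNase-seq and MNase-H3, pooled per cell-cycle state and MNase concentration, on a scale that is not stated (another unit than counts or TPM). The ChIP-seq libraries enter no comparison and were not analysed here.

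The count table has 37620 genes, of which 32897 Ensembl IDs (87.4%) matched the symbol reference, and 3730 entries share a symbol with another. Genes were filtered with filterByExpr by group, which kept 16011. Counts were scaled by TMM and tested in edgeR 4.0.16 with a quasi-likelihood F test (robust) on a group-means model of all 18 libraries, with 12 residual degrees of freedom and a biological coefficient of variation of 0.14. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F, and CPM are counts scaled by the TMM-scaled library size. The contrasts were auxin against none in each phase and averaged over phases, the 3 differences of the auxin effect between phases, and the 3 differences between phases without auxin.

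Total counts of 24841963 to 37587322 per library give the depth. Within a group, the chi-square per degree of freedom between libraries was 14.7 to 53.9 for genes with at least 20 counts, so replicates spread far more than counting error. Tested on simulated data with the fitted dispersions, the test recovered 38.9% of genes changed 1.5-fold and 62.9% of genes changed 2-fold for auxin in early G1, 42.2% and 64.8% in late G1, 39.3% and 68.8% in G2, and 69.5% and 88.4% in the average. For the differences between phases it recovered 10.2% and 42.2% (early against late G1), 22.5% and 44.9% (early G1 against G2) and 14.7% and 52.4% (late G1 against G2). In those simulations, with 200 changed genes, it also called 9, 8, 7 and 5 unchanged genes for auxin in early G1, late G1, G2 and the average, 2, 5 and 0 for the differences of the auxin effect, and 0, 4 and 10 for late minus early G1, G2 minus early G1 and G2 minus late G1. It made 0 calls when nothing was changed. The simulated libraries were independent, without the correlation between libraries of the same number described next, so these rates may not hold for the real data.

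Whether replicate numbers pair libraries is not stated in the labels, so it was checked from the values, as the correlation of deviations from group means between libraries of the same number in different groups. Every one of the 18 libraries correlated best, on average, with its own number. A contrast was taken as paired when every same-number pair exceeded 0.1, which held for auxin in early G1 (0.26 to 0.29) and late G1 (0.22 to 0.29), for early against late G1, and for the 3 differences between phases without auxin (0.22 to 0.50), but not where G2 with and without auxin entered (lowest 0.05). Blocked counts stand beside the paired contrasts, and the unblocked model stayed the reported one as planned. The blocked counts had been seen when that limit was set.

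Named genes are up to 10 that rose and 10 that fell in each auxin or cell-cycle contrast, with the largest fitted change among called genes whose 2 groups do not overlap in CPM (for the average, with the same sign in all phases) and with an average log2 CPM of at least 1, without unnamed gene models. Up to 5 each way were allowed for a difference between phases, without the overlap condition. Up to 4 members of a list with the smallest p were added where the list passed or had called members, and Sox2 in every library. A few genes that met this rule are not reported here. The 27 lists cover pluripotency, lineages, signalling, stress, cell cycle, housekeeping and chromatin genes. They were tested with camera (limma 3.58.1, preset correlation 0.01) and, as alternatives, with an estimated correlation, fry, and the replicate block. Lists with fewer than 5 tested genes were not tested. A list took every tested entry with a listed symbol. Entries that share a symbol therefore count separately in the sizes and counts of a list.

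Profiles were read at every 10 bp from -1000 to 1000. The planned smoothing over 11 positions assumed values at each base pair and was not run. The authors' own smoothed curve was used as the reported setting, and their unsmoothed midpoint or cut-site values as the alternative. The centre is the mean within 50 bp, the flank that from 80 to 1000 bp on both sides, and the amplitude the SD along the flank after removal of a linear trend, in percent of the flank mean. A reversal was read only where the reported log2 change was at least 0.2 in size, whatever the size in the alternative, a floor chosen after the values and the number of reversals it removes had been seen.

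Alternatives were median-of-ratios size factors, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma on log2 TPM with a pseudocount of 1 or 0.1, the replicate block, the contrast's groups alone, an adjusted p under 0.01, each library left out, and other profile windows. Leaving out the untreated libraries numbered 3 and the fry tests of effect size were added after the data were seen. Calculations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.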

Results

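The study asked how transcription factors and nucleosomes behave when mouse embryonic stem (ES) cells pass through mitosis, and what loss of Sox2 does to gene expression at successive stages of the cell cycle. It holds 97 libraries: 36 of ChIP-seq for Esrrb, Nanog, Sox2 and Oct4, 9 of ChIP input, 18 of MNase-seq, 12 of MNase digestion followed by histone H3 immunoprecipitation (MNase-H3), 4 of ATAC-seq and 18 of RNA-seq. The RNA came from a Sox2-AID line, in which Sox2 carries an auxin-inducible degron, a tag through which auxin leads to destruction of the tagged protein. Cells had 0.5 mM auxin for 3 h or none, received 20 µM Hoechst in the last 20 min, and were sorted into early G1, late G1 and G2. Each of the 6 groups has 3 libraries, so every RNA value below is from n = 3 per group.

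Total counts ran from 24841963 (untreated late G1, replicate 3) to 37587322 (auxin-treated G2, replicate 1). In early G1, replicates 1, 2 and 3 had totals of 32765169, 28905098 and 27052996 without auxin and 33985790, 30989673 and 30961630 with it. Late G1 had 35787324, 30135016 and 24841963 without and 37148365, 28539463 and 29581104 with auxin. G2 had 31246791, 28465172 and 26036310 without and 37587322, 34111100 and 33185511 with it. The non-coding gene AC157822.1 held 15.8% to 21.2% of all counts in a library, 7SK held 3.71% to 4.76% and RNase_MRP 2.34% to 4.20%. On the first principal component, with 17.6% of the variance, the untreated libraries numbered 3 stood apart from the others of their groups, at 31.1 in early G1, 52.4 in late G1 and 29.3 in G2. They also had the lowest total of their groups. Replication-dependent histone genes held 1.32% ± 0.38 of counts in untreated late G1, against 0.412% ± 0.042 in early G1 and 0.511% ± 0.12 in G2.

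Sox2 messenger RNA was present in every library with and without auxin. Untreated early G1 libraries had 294, 343 and 395 CPM (counts scaled by library size) and auxin-treated ones 317, 393 and 397. Late G1 libraries had 291, 393 and 389 CPM without auxin and 330, 394 and 413 with it. In G2 the values were 277, 322 and 368 CPM without auxin and 314, 365 and 345 with it. Averaged over phases, the log2 fold change of Sox2 was 0.09 ± 0.08 (SE, edgeR adjusted p 0.527), and that of Pou5f1, which encodes Oct4, was 0.06 ± 0.07 (adjusted p 0.656). Between libraries of the same replicate number, Sox2 CPM was higher with auxin in 3 of 3 pairs in early G1, 3 of 3 in late G1 and 2 of 3 in G2. On TPM it was lower with auxin in 7 of 9 pairs, so its direction depends on the scaling. The median log2 change over all tested genes was itself below 0 on TPM, at -0.08 in the average with a pseudocount of 1. With the replicate block its log2 fold change was 0.1 ± 0.06 in early G1 (adjusted p 0.42) and 0.09 ± 0.06 in late G1 (0.415). Auxin acts on the Sox2 protein, so the Sox2 transcript checks neither the depletion nor the labels.

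In early G1, the first phase after mitosis, auxin raised the transcription factors Gata2 and Irf5 and the sulfatase Arsi most among called genes with an average log2 CPM of at least 1 and lowered Kbtbd11 and D16Ertd472e. Gata2 went from 0.806 ± 0.30 to 2.80 ± 1.1 CPM (SD), a log2 fold change of 1.79 ± 0.34 (SE, edgeR adjusted p 0.0445). Arsi rose by 1.51 ± 0.26 and Irf5 by 1.35 ± 0.25, and Ngfr (0.83 ± 0.09), Irf1 (0.73 ± 0.10), Zbtb46 (0.69 ± 0.11), Btg2 (0.61 ± 0.10), Klf10 (0.59 ± 0.07) and Slc30a2 (0.50 ± 0.09) rose less. Kbtbd11 fell from 49.9 ± 5.6 to 22.7 ± 3.9 CPM, a log2 fold change of -1.13 ± 0.15 (adjusted p 0.0016). D16Ertd472e changed by -0.69 ± 0.10. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor and below the expression floor for that ranking, rose from 0.334 ± 0.081 to 1.95 ± 0.27 CPM (log2 fold change 2.54 ± 0.33, adjusted p 0.0016). Icam1 (0.46 ± 0.08) and Id1 (0.50 ± 0.09) also passed, while Gbx2 (-1.23 ± 0.24, adjusted p 0.0605) and Jam2 (-0.34 ± 0.07, adjusted p 0.0589) did not. In all, 13 genes rose and 4 fell of 16011 tested, and 255 passed with the replicate number as a block (123 up, 132 down). The 17 genes had no overlap between treated and untreated libraries, a condition that 11.3% of all tested genes met, with 10% given by chance. The count was 10 without auxin-treated replicate 2, 6 without auxin-treated replicate 3, 8 without untreated replicate 2, 10 without untreated replicate 3, and 9 without the untreated libraries numbered 3 of all phases. Gata2 lost its call in 5 of 6 leave-outs of a library (adjusted p up to 0.283, without untreated replicate 3). Irf5 (4 of 6, up to 0.279), Slc30a2 (4 of 6, 0.265) and Btg2 (3 of 6, 0.126), each highest without untreated replicate 2, and Arsi (4 of 6, 0.168), Zbtb46 (4 of 6, 0.117) and D16Ertd472e (1 of 6, 0.0812), each highest without auxin-treated replicate 3, lost theirs too. With the stricter low-count filter 13 rose and 7 fell, DESeq2 called 29 up and 21 down, and on TPM with a pseudocount of 1 only Cyp1a1 rose and Gm5101, a gene named after its values were seen, fell.

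In late G1, Kbtbd11 and the naive pluripotency factors Klf2, Gbx2 and Klf4 fell and Gata2, Arsi and Trim63 rose. Klf2 went from 5.33 ± 1.2 to 1.21 ± 0.47 CPM (log2 fold change -2.14 ± 0.38, edgeR adjusted p 0.00737) and Kbtbd11 from 60.3 ± 8.7 to 17.8 ± 2.9 CPM (-1.76 ± 0.15, adjusted p 5.74e-06). Gbx2 changed by -1.72 ± 0.24, Klf4 by -1.37 ± 0.21, Arid5b by -1.28 ± 0.23, Paqr8 by -1.16 ± 0.17, Cnpy1 by -1.13 ± 0.20, Kdr by -1.02 ± 0.23 and Fzd5 by -0.95 ± 0.15. Gata2 rose to 3.88 ± 1.1 CPM from 0.879 ± 0.19 (2.12 ± 0.33, adjusted p 0.00199), and Arsi by 1.88 ± 0.26 (adjusted p 0.000641). Trim63 (1.48 ± 0.22), Meox1 (1.47 ± 0.31), Mmp28 (1.42 ± 0.18), Hrh3 (1.33 ± 0.27), Irf5 (1.3 ± 0.24), Camk2n1 (1.28 ± 0.18), Fam46b (1.28 ± 0.16) and Eomes (1.14 ± 0.26) rose too. Among pluripotency genes, Nanog fell from 207 ± 8.5 to 160 ± 1.4 CPM (-0.37 ± 0.08, adjusted p 0.0226), and Zfp42 (-0.46 ± 0.09), Fgf4 (-0.47 ± 0.11), Nr5a2 (-0.85 ± 0.11), Tet2 (-0.71 ± 0.10) and Jam2 (-0.57 ± 0.07) passed as well. Pou3f1 rose by 1.08 ± 0.20, Dlx3 by 3.02 ± 0.60 and Cyp1a1 by 2.72 ± 0.38. In all, 79 genes rose and 84 fell, and 952 passed with the replicate block (404 up, 548 down). The count was 106, 95 and 72 without auxin-treated replicates 1, 2 and 3, and 87 and 84 without untreated replicates 2 and 3. Calls were lost in leave-outs of a library by Kdr (5 of 6, adjusted p up to 0.229) and Hrh3 (5 of 6, 0.0984), highest without untreated replicate 3, Irf5 (2 of 6, 0.0549, untreated replicate 2), Eomes (5 of 6, 0.208), Klf2 (1 of 6, 0.0608) and Cnpy1 (1 of 6, 0.0634), highest without auxin-treated replicate 3, Meox1 (4 of 6, 0.101, auxin-treated replicate 2) and Arid5b (3 of 6, 0.0552, auxin-treated replicate 1). On TPM with a pseudocount of 1, 3 genes rose and 6 fell.

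In G2, Klf2, Gbx2 and Kbtbd11 fell and Gata2 and Gcnt4 rose. Klf2 went from 6.32 ± 0.76 to 1.17 ± 0.65 CPM (log2 fold change -2.42 ± 0.37, edgeR adjusted p 0.00313), Gbx2 changed by -1.60 ± 0.24 and Kbtbd11 by -1.56 ± 0.15. Fam196a (-1.28 ± 0.28), Klf4 (-1.14 ± 0.21), Kdr (-1.11 ± 0.22), Cnpy1 (-1.11 ± 0.20), AY036118 (-1.0 ± 0.18) and Cdc42ep3 (-0.97 ± 0.19) fell as well. Gata2 rose from 0.681 ± 0.15 to 3.54 ± 0.79 CPM (2.37 ± 0.34, adjusted p 0.00167). Gcnt4 (2.21 ± 0.40), Meox1 (1.55 ± 0.31), Arsi (1.48 ± 0.26), Irf5 (1.43 ± 0.25), Eomes (1.42 ± 0.27), Cacna1h (1.35 ± 0.30), Camk2n1 (1.32 ± 0.19), Sema3f (1.25 ± 0.26) and Sema3b (1.23 ± 0.19) rose. Sox8 (1.34 ± 0.29), Pou3f1 (1.20 ± 0.21) and Cyp1a1 (2.90 ± 0.39) rose and Mycn (-0.78 ± 0.14) fell, while Nanog (-0.34 ± 0.08) missed the threshold at an adjusted p of 0.0512. In all, 62 genes rose and 45 fell. The count was 70 and 54 without auxin-treated replicates 1 and 3, and 64, 56 and 60 without untreated replicates 1, 2 and 3. Meox1 lost its call in 6 of 6 leave-outs of a library (adjusted p up to 0.137, without untreated replicate 1). Calls were also lost by Cacna1h (5 of 6, 0.235), Sema3f (5 of 6, 0.167), Arsi (2 of 6, 0.0591) and Irf5 (1 of 6, 0.0575), highest without untreated replicate 2, by Fam196a (5 of 6, 0.208), Kdr (4 of 6, 0.128) and Gcnt4 (1 of 6, 0.0648), highest without untreated replicate 3, and by Cdc42ep3 (5 of 6, 0.129), Klf4 (4 of 6, 0.108), Eomes (3 of 6, 0.0945), Cnpy1 (2 of 6, 0.0924) and AY036118 (3 of 6, 0.0915), highest without auxin-treated replicate 3. On TPM with a pseudocount of 1, 0 genes rose and 8 fell.

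**Figure D1:**
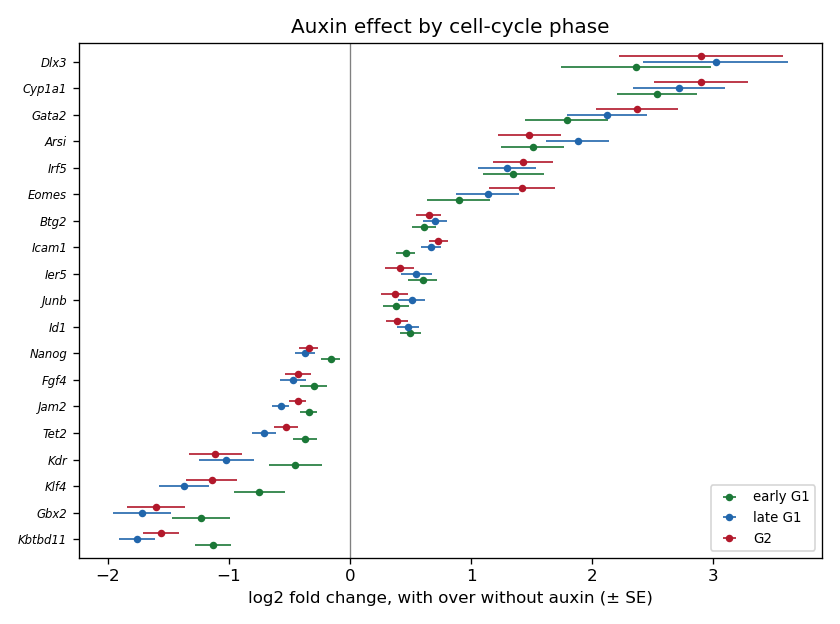
Log2 fold change with over without auxin (x axis, ± SE, n = 3 libraries per group) for 19 genes. Each was picked by the naming rule in every phase, by size or from a list, and passed the test in at least 1 phase. Genes picked in fewer phases are not shown. Kbtbd11 lies at -1.13 in early G1 and -1.76 in late G1, and Gata2 at 1.79 and 2.12.

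Averaged over the 3 phases, auxin lowered Klf2, Gbx2, Kbtbd11 and Klf4 and raised Gata2, Arsi, Gcnt4 and Irf5. Klf2 changed by -1.94 ± 0.21 on the log2 scale, Gbx2 by -1.52 ± 0.14, Kbtbd11 by -1.48 ± 0.09 (edgeR adjusted p 7.26e-09), Zfhx2 by -1.15 ± 0.20, Fam196a by -1.09 ± 0.16, Klf4 by -1.09 ± 0.12, Cnpy1 by -1.02 ± 0.12 and Arid5b by -1.0 ± 0.13. Gata2 rose by 2.09 ± 0.20 (adjusted p 2.18e-06), Arsi by 1.63 ± 0.15, Gcnt4 by 1.45 ± 0.22, Irf5 by 1.36 ± 0.14, Tinagl1 by 1.25 ± 0.24, Meox1 by 1.22 ± 0.18, Hrh3 by 1.20 ± 0.16, Wnt7b by 1.18 ± 0.24, Pdgfb by 1.16 ± 0.17 and Eomes by 1.16 ± 0.15. Of the pluripotency factors bound in the study's ChIP libraries, Nanog changed by -0.29 ± 0.04 (adjusted p 0.000532) and Esrrb by -0.24 ± 0.07 (adjusted p 0.0477). Polr2a, from the housekeeping list, changed by -0.48 ± 0.10 (adjusted p 0.0049). In all, 416 genes rose and 494 fell (358 and 253 without the untreated libraries numbered 3), and the named genes with the largest changes kept their call in every leave-out of a library. The SE and adjusted p of the average take all libraries as independent. Same-number libraries correlated, however, with means of 0.36 between untreated groups, 0.26 between auxin-treated groups and 0.21 between treated and untreated groups. The average was not refitted without a whole replicate number. On TPM with a pseudocount of 1 the balance was 61 up and 716 down, with a median log2 change over all tested genes of -0.08 (-0.16 with a pseudocount of 0.1), against 0.006 on counts.

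Of the gene lists fixed before the data were examined, naive pluripotency genes had the smallest camera p in the average: 15 of 22 fell and 0 rose (18 fell when adjusted over the list alone), with a median of -0.37 and a camera adjusted p of 5.61e-29. Jam2 (-0.45 ± 0.04), Tet2 (-0.54 ± 0.05) and Nr5a2 (-0.63 ± 0.06) were among them. Core pluripotency had 5 of 20 down, Nanog, Fgf4 (-0.40 ± 0.06) and Sall4 (-0.53 ± 0.11) included (camera adjusted p 0.00158; adjusted over the list alone 1 up and 5 down). The classic Sox2 and Oct4 co-targets had 4 down, Klf2 and Zfp42 (-0.34 ± 0.05) among them, and 1 up of 19 (0.0286; list alone 3 up and 5 down). In the trophectoderm list Gata2, Eomes, Dlx3 (2.76 ± 0.37) and Cdx2 (1.22 ± 0.19) led 6 genes up against 1 down of 16 (8.3e-08; list alone 9 up and 1 down). Immediate early and stress genes had 8 up of 21, with Btg2 at 0.66 ± 0.06, Ier5 at 0.52 ± 0.07 and Junb at 0.42 ± 0.06 (1.42e-07; list alone 11 up and 1 down). With an estimated correlation between genes, the naive (0.000701), core (0.0196), trophectoderm (0.00588) and immediate early (0.00783) lists still passed, and the co-targets did not (0.0776). The p53 targets (4 up, camera 0.0135, estimated 0.201; list alone 7 up and 2 down), germline and 2-cell-like genes (0 called, 0.0157 and 0.371) and cytosolic ribosomal proteins (0 called, 5.18e-06 and 0.649) passed with the preset correlation only. All 34 ribosomal protein genes had a positive change on counts (median 0.13), and 3 of 34 on TPM (median -0.07), so their direction depends on the scaling. On TPM the median over all tested genes was also below 0, at -0.08 with a pseudocount of 1 and -0.16 with 0.1. Against that median the ribosomal protein genes were not lower.

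The other lists did not pass camera in the average of the unblocked fit. Formative and primed pluripotency had 3 up, Pou3f1 (1.02 ± 0.12), Cldn6 (0.41 ± 0.06) and Tead2 (0.14 ± 0.04), of 21. The direction of Tead2 depends on the scaling, at -0.11 on TPM. The mesoderm and endoderm list had Eomes, Snai1 (0.96 ± 0.16) and Wnt3 (0.92 ± 0.26) up and Kdr (-0.86 ± 0.13) down of 8, neuroectoderm had Nes (0.38 ± 0.09) up of 6, and primitive endoderm had Sox7 (0.77 ± 0.18) up of 16. In the Sox family Sox8 (1.03 ± 0.17), Sox9 (1.75 ± 0.47) and Sox18 (1.18 ± 0.33) rose of 14 (list alone 3 up and 2 down). FGF-ERK targets had Dusp4 (0.50 ± 0.08), Fos (0.64 ± 0.13) and Dusp5 (0.74 ± 0.20) up of 18 (list alone 3 up and 2 down), LIF-STAT3 targets had 2 up, Icam1 (0.62 ± 0.05) and Junb, and 4 down, Gbx2 and Klf4 included, of 16 (list alone 4 up and 4 down), and Wnt targets had Wnt3 up and Notum (-0.88 ± 0.25) down of 14. Nodal and BMP targets had 4 up, Id1 (0.45 ± 0.05), Smad6 (0.53 ± 0.11) and Lefty2 (1.07 ± 0.24) among them, and Smad7 (-0.65 ± 0.12) down of 13 (list alone 6 up and 3 down). Among aryl hydrocarbon receptor targets Cyp1a1 (2.72 ± 0.21) and Nqo1 (0.25 ± 0.06) rose and Ahr (-0.54 ± 0.13) fell of 8 (list alone 3 up and 2 down). Ddit3 (0.44 ± 0.11) rose in the unfolded protein and integrated stress response list of 16, Tet2 and Tet1 (-0.35 ± 0.09) fell among 17 DNA methylation and Polycomb genes, and Mycn (-0.60 ± 0.08) and Ncl (-0.20 ± 0.05) fell among 18 Myc and ribosome biogenesis genes (list alone 3 down). In the housekeeping list of 15, Polr2a was the only gene past the threshold over all genes (list alone 1 up and 1 down). None of the 12 fibroblast or feeder cell genes, 26 G1/S genes, 37 G2/M genes, 71 replication-dependent histone genes and 15 genes of the mitochondrial genome passed, adjusted over the list alone or over all genes.

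Naive pluripotency also had the smallest camera p in each single phase. In early G1 camera gave naive pluripotency an adjusted p of 3.48e-14 (median -0.25; 0 called, 7 down adjusted over the list alone), trophectoderm 1.4e-05 and immediate early genes 3e-06, and these 3 held with an estimated correlation (0.0157, 0.0167 and 0.0167). Cytosolic ribosomal proteins (7.26e-06, estimated 0.603), mesoderm and endoderm (0.00756 and 0.0696), germline and 2-cell-like (0.00756 and 0.354), primitive endoderm (0.0171 and 0.565), core pluripotency (0.027 and 0.102) and p53 targets (0.0482 and 0.354) passed there with the preset correlation only. Naive pluripotency had 9 genes down in late G1 (3.31e-27; list alone 14) and 6 down in G2 (2.73e-25; list alone 13). With an estimated correlation it passed in late G1 (0.000902), with immediate early genes (0.0146), trophectoderm (0.0151) and core pluripotency (0.0187), and in G2 (0.00132), with trophectoderm (0.00556). In late G1, ribosomal proteins (2.18e-06, estimated 0.606), p53 targets (0.0113 and 0.219), co-targets (0.0312 and 0.0751) and germline genes (0.0453 and 0.52), and in G2 immediate early genes (0.000311 and 0.051), core pluripotency (0.0107 and 0.051), ribosomal proteins (0.0202 and 0.666) and co-targets (0.0203 and 0.051), passed with the preset only. With the replicate block the Nodal and BMP targets also passed in early G1 (0.0106, against 0.259 with an estimated correlation and no block), and in late G1 the Nodal and BMP targets (0.0314 against 0.386), mesoderm and endoderm genes (0.0314 against 0.386), DNA methylation and Polycomb genes (0.00961 against 0.15) and Myc and ribosome biogenesis genes (0.0366 against 0.714) did.

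The series asks whether Sox2 matters most after mitosis, so the auxin effect was compared between phases. For single genes, edgeR called 0 for early G1 against late G1, early G1 against G2, and late G1 against G2. At an unadjusted p under 0.05 there were 222, 222 and 218 genes, below the share that chance gives, and limma on TPM called 0 in each. With the replicate block 523, 526 and 498 genes had such an edgeR p, also below that share. In the simulations, whose libraries were independent, the edgeR test recovered 10.2%, 22.5% and 14.7% of genes with 1.5-fold differences. Those rates may not hold for the real libraries, which correlated by number. The 0 calls therefore do not show that no gene differed. DESeq2 called 1, 0 and 0 genes, and the fit with the replicate block called 1 for early G1 against late G1. Both of those calls were Lgr4, a gene named after its values were seen, with an auxin effect of -0.27 ± 0.08 in early G1 and -0.83 ± 0.08 in late G1, a difference of 0.56 ± 0.11 (edgeR adjusted p 0.787, blocked 0.0382). The 17 genes called in early G1 were also called in late G1 and in G2, all in the same direction, among them Arsi, Btg2, Cyp1a1, D16Ertd472e, Gata2, Gm5101, Icam1, Id1, Irf1, Irf5, Kbtbd11, Klf10, Ngfr, Slc30a2 and Zbtb46. Late G1 and G2 shared 78 calls, all in the same direction, where independent lists would share 0.542 in the same direction. The lists are not independent, since they came from 1 fit and same-number libraries correlated across phases.

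Genes called in a given phase had their effects compared between the other 2 phases. The 163 genes called in late G1 had a median absolute log2 change, taken along the direction in late G1, of 0.44 in early G1 and 0.64 in G2, and 85.3% of them changed less in early G1. The median of the difference was -0.18, and its values from single replicate numbers were -0.164, -0.220 and -0.169 (SD 0.0308). With the replicate block, whose 952 called genes are a different set, it was -0.07. The 107 genes called in G2 had medians of 0.49 in early G1 and 0.81 in late G1, with a median difference of -0.30 (SD 0.0169) and 88.8% smaller in early G1. Klf2, an example, had log2 changes of -1.26 ± 0.35 in early G1, -2.14 ± 0.38 in late G1 and -2.42 ± 0.37 in G2, and the difference between early G1 and G2 did not pass (1.16 ± 0.51, edgeR adjusted p 1). The 17 genes called in early G1 had similar medians in late G1 (0.99) and G2 (0.92). Across the 11471 genes with an average log2 CPM of at least 1, Pearson correlations of fold changes were 0.65 for early against late G1, 0.69 for early G1 against G2 and 0.72 for late G1 against G2 (Spearman 0.72, 0.67 and 0.68). Over all 16011 tested genes the Pearson values were 0.44, 0.38 and 0.41. The order of the 3 depends on the genes and the measure. Those are across genes, which are not independent replicates.

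Without auxin, and among the named genes and lists, late G1 differed from early G1 most in histone and DNA replication genes. Hist1h2af rose from 10.2 ± 3.0 to 82.5 ± 26 CPM (log2 fold change 3.01 ± 0.48, edgeR adjusted p 0.00197), with Hist1h2bh (2.82 ± 0.48), Hist1h1b (2.54 ± 0.41), Hist1h3b (2.53 ± 0.36), Hist1h1e (2.47 ± 0.60), Hist1h2bl (2.47 ± 0.44), Hist1h2bn (2.40 ± 0.49), Hist1h2ab (2.37 ± 0.33), Hist1h2bm (2.33 ± 0.33) and Hist1h2bg (2.29 ± 0.48) next. Histone genes and the Zscan4 family hold near-identical copies, so the share of each copy is uncertain. Of 71 histone genes 52 rose (list alone 61; camera adjusted p 2.97e-72, and 0.0661 with an estimated correlation), and of 26 G1/S genes 21 rose (list alone 24), Chaf1b by 0.91 ± 0.09, Cdc45 by 0.82 ± 0.10, Pcna by 0.75 ± 0.09 and Ung by 0.70 ± 0.09. Sema4c (-2.14 ± 0.27), Dub1a (-1.70 ± 0.29), Fam64a (-1.53 ± 0.14), Gadd45g (-1.53 ± 0.29), Rnf103 (-1.48 ± 0.18), Prr11 (-1.43 ± 0.13), Zscan4e (-1.33 ± 0.19), Zscan4-ps2 (-1.32 ± 0.28), Slco4c1 (-1.32 ± 0.26) and Sh2d4a (-1.3 ± 0.24) were lower in late G1. Of 37 G2/M genes 16 were lower, Cenpa (-1.16 ± 0.10) included, and 4 were higher, Aurkb (1.60 ± 0.16) and Top2a (1.15 ± 0.11) among them. Among pluripotency genes Pecam1 fell from 77.7 ± 1.4 to 41.0 ± 0.94 CPM (-0.92 ± 0.06) and Nanog from 270 ± 18 to 207 ± 8.5 CPM (-0.39 ± 0.08). Immediate early genes were lower, with Jun at -0.94 ± 0.13, Klf6 at -0.93 ± 0.14 and Atf3 at -0.89 ± 0.17 (camera adjusted p 1.1e-07, estimated 0.0137). Of the 9 lists past camera, G1/S genes (estimated 0.0137) and immediate early genes held with an estimated correlation. In all, 523 genes rose and 601 fell, and 3487 passed with the replicate block (1823 up, 1664 down). The count was 684 and 641 without early G1 replicates 1 and 2 and 662 without late G1 replicate 2, and 594 without the untreated libraries numbered 3. Hist1h1e (4 of 6 leave-outs, adjusted p up to 0.0946, without early G1 replicate 3) and Hist1h2bg (2 of 6, 0.054, early G1 replicate 1) lost their call. On TPM with a pseudocount of 1 the count was 81 up and 158 down.

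Among the named genes, G2 differed from early G1 most in mitotic genes, again without auxin. The mitotic kinase gene Aurkb rose from 10.7 ± 2.8 to 74.5 ± 3.8 CPM (log2 fold change 2.80 ± 0.16, edgeR adjusted p 2.74e-09), followed by Kpna2 (2.60 ± 0.12), Top2a (2.50 ± 0.12), Prc1 (2.46 ± 0.11), Ube2c (2.04 ± 0.26), Cdk1 (1.93 ± 0.15), Fbxo5 (1.62 ± 0.08), Depdc1b (1.48 ± 0.19), Hn1 (1.47 ± 0.11) and Fam83d (1.46 ± 0.13). Of 37 G2/M genes 22 rose and 0 fell (list alone 31 up; camera adjusted p 1.08e-68, estimated 0.00587). Egr1 (-2.03 ± 0.48), Camk2n1 (-1.75 ± 0.19), Gcnt4 (-1.58 ± 0.41), Chrm4 (-1.55 ± 0.25), Chrnb2 (-1.45 ± 0.23), Fos (-1.25 ± 0.24), Col11a2 (-1.20 ± 0.31), Mttp (-1.19 ± 0.16), Efnb3 (-1.16 ± 0.26) and Cd24a (-1.16 ± 0.19) were lower in G2. Immediate early genes had 7 down of 21 (list alone 11; camera 5.79e-09, estimated 0.00599), Jun at -0.92 ± 0.13 and Junb at -0.68 ± 0.11. Ccne2 fell from 25.0 ± 2.5 to 12.5 ± 0.53 CPM (-1.0 ± 0.10), and Nanog changed by -0.34 ± 0.08. Core pluripotency (0.035), LIF-STAT3 targets (0.0268), p53 targets (0.0363) and DNA methylation and Polycomb genes (0.0294) passed camera only with the replicate block, against 0.29, 0.64, 0.552 and 0.266 with an estimated correlation and no block. In all, 304 genes rose and 272 fell, and 2360 passed with the replicate block (1247 up, 1113 down). The count was 331, 309 and 258 without early G1 replicates 1, 2 and 3, 293 and 241 without G2 replicates 1 and 2, and 213 without the untreated libraries numbered 3. Col11a2 (4 of 6 leave-outs, adjusted p up to 0.182), Gcnt4 (5 of 6, 0.167), Egr1 (4 of 6, 0.134) and Efnb3 (4 of 6, 0.0935) lost their call, each with the highest value without early G1 replicate 3.

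Against late G1, G2 had higher mitotic genes and lower histone and G1/S genes. Prr11 (log2 fold change 2.33 ± 0.13, edgeR adjusted p 5.86e-09), Nusap1 (2.29 ± 0.13), Ube2c (2.21 ± 0.26), Fam83d (1.99 ± 0.13), Aurka (1.94 ± 0.13), Fhl2 (1.81 ± 0.35), Arl6ip1 (1.79 ± 0.13), Depdc1b (1.70 ± 0.19), Sun2 (1.65 ± 0.15) and Cdc25b (1.61 ± 0.18) were the named genes that rose. Hist1h2bq (-2.18 ± 0.41), Hist1h2bn (-2.17 ± 0.49), Hist4h4 (-2.06 ± 0.44), Hist1h2bg (-2.00 ± 0.47), Hist1h2be (-1.94 ± 0.39), Hist1h2bl (-1.92 ± 0.43), Hist1h2af (-1.89 ± 0.45), Hist1h2bh (-1.88 ± 0.46), Egr1 (-1.87 ± 0.48) and Hist1h2bm (-1.85 ± 0.32) fell. Of 37 G2/M genes 35 rose (estimated-correlation camera adjusted p 0.000407), of 26 G1/S genes 17 fell (0.00985; list alone 22), and of 71 histone genes 46 fell (0.155; list alone 62). Ccne2 changed by -1.66 ± 0.10, Chaf1b by -1.06 ± 0.09, Fst by 1.20 ± 0.17, Klf6 by 1.09 ± 0.14 and Pecam1 by 0.82 ± 0.06. In all, 436 genes rose and 371 fell, and 2541 passed with the replicate block (1294 up, 1247 down). The count was 445 without late G1 replicate 2, 485 and 465 without G2 replicates 1 and 2, and 494 without the untreated libraries numbered 3. On TPM with a pseudocount of 1 it was 151 up and 51 down. Calls were lost by Hist1h2bh (4 of 6 leave-outs, adjusted p up to 0.135), Hist1h2af (4 of 6, 0.113), Hist1h2bn (3 of 6, 0.0932), Hist1h2bl (3 of 6, 0.0844) and Hist1h2be (1 of 6, 0.053), highest without G2 replicate 1, by Hist1h2bg (4 of 6, 0.103) and Hist4h4 (3 of 6, 0.0668), highest without late G1 replicate 2, and by Egr1 (5 of 6, 0.158), highest without late G1 replicate 3.

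**Figure D2:**
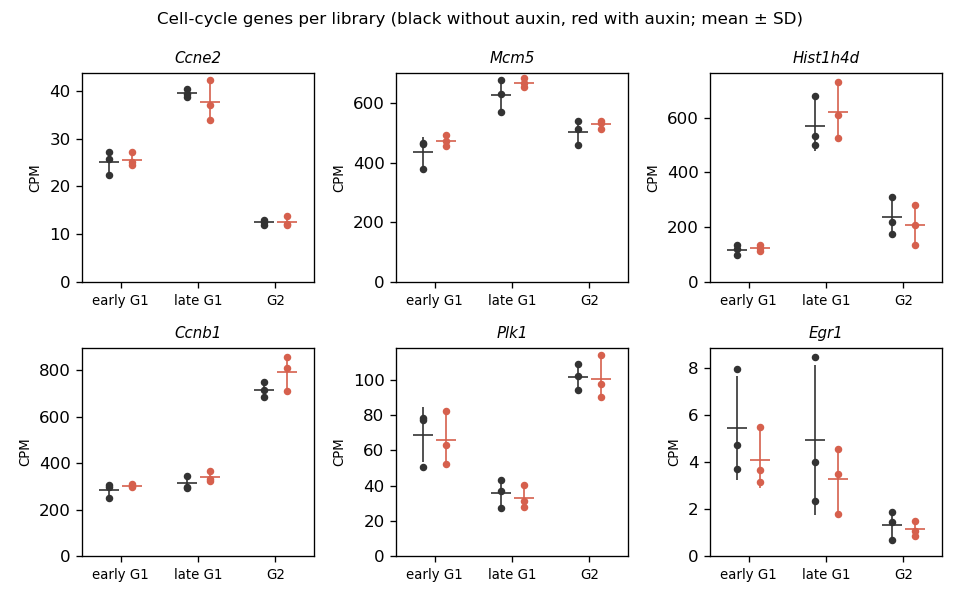
CPM (y axis, from 0) of 6 cell-cycle and immediate early genes in each library, without auxin in black and with auxin in red, with the mean ± SD of the 3 libraries of each group. Ccne2 peaks in late G1 (39.5 without auxin), Hist1h4d reaches 570 there, and Ccnb1 reaches 717 in G2.

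ATAC-seq profiles, pooled per cell-cycle state by the authors, addressed accessibility in mitosis, and having no replicates they carry no error or test. The centre, within 50 bp of the site, was compared with the flank from 80 to 1000 bp. Centre-to-flank ratios were lower in mitosis at 4 of 5 site classes: from 2.86 to 2.26 at EP300 summits, from 1.47 to 1.17 at Esrrb_Book summits, from 2.23 to 1.48 at Esrrb_Lost summits and from 2.21 to 1.40 at Oct4/Sox2 summits. At transcription start sites (TSS) the ratio was 2.60 in interphase and 2.67 in mitosis.

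MNase-seq profiles addressed nucleosome arrays through the amplitude of the signal along the flank, in percent of its mean. The amplitude takes in any departure from a straight line and measures no period, so it is not specific to arrays. Around Oct4/Sox2 motifs the amplitude was lower in mitosis at each MNase concentration, from 5.19% to 2.15% at 0.5, from 6.55% to 2.47% at 16 and from 6.20% to 3.70% at 128 (no unit is given for the concentrations). Without smoothing the log2 changes for Oct4/Sox2 were -0.5, -0.47 and -0.06. Around Esrrb_Book motifs it was higher in mitosis, from 4.00% to 5.82%, from 4.52% to 6.69% and from 3.23% to 6.67%. At TSS it fell from 10.1% to 7.77%, from 12.2% to 7.68% and from 11.9% to 5.15%. At EP300 summits it fell from 4.07% to 1.78% at 0.5 and from 3.91% to 2.34% at 16, and rose from 2.39% to 5.36% at 128. The fall at 16 was absent without smoothing, at a log2 change of 0.08. In all, 15 of 21 profiles had a lower amplitude and 8 of 21 a lower centre-to-flank ratio in mitosis (5 with a centre within 100 bp). By at least 0.2 on the log2 scale, 14 had a lower and 6 a higher amplitude, and 0 a lower and 3 a higher ratio. Without smoothing, some of the 15 amplitudes were no longer lower. The centre value as deposited, which is not divided by the flank, was lower in mitosis in 12 profiles.

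**Figure D3:**
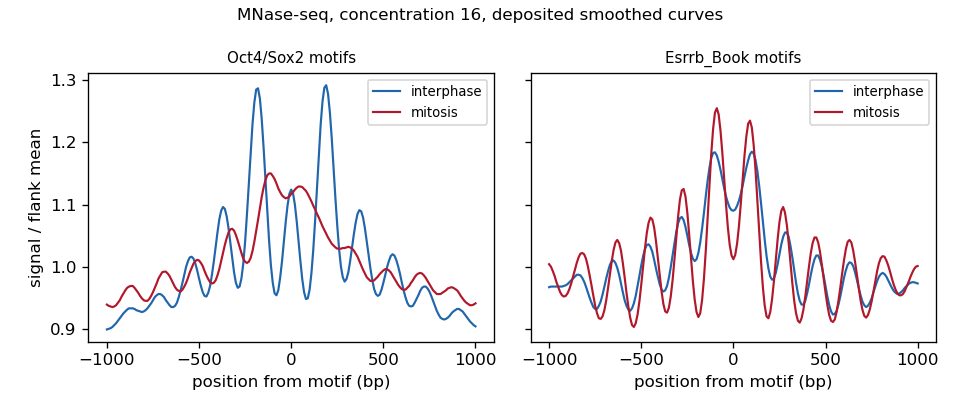
MNase-seq signal at concentration 16 divided by its flank mean (y axis) against position in bp (x axis), as the authors' smoothed pooled curves, around Oct4/Sox2 motifs (left) and Esrrb_Book motifs (right), interphase in blue and mitosis in red. The flank amplitude went from 6.55% to 2.47% on the left and from 4.52% to 6.69% on the right.

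MNase-H3 profiles addressed nucleosomes that hold histone H3. The ratio of centre to flank was higher in mitosis in 19 of 21 profiles (2 lower, but 5 lower with a centre within 25 bp and 0 with one within 100 bp; by at least 0.2 on the log2 scale 6 higher and 0 lower), most at TSS and EP300 summits: from 0.402 to 0.699 at TSS and from 0.765 to 1.20 at EP300 summits at concentration 128, and from 0.360 to 0.489 and from 0.617 to 0.957 at 16. At 0.5 it went from 0.363 to 0.407 at TSS and from 0.590 to 0.637 at EP300 summits. At Oct4/Sox2 motifs it went from 1.03 to 1.06, from 1.00 to 1.13 and from 0.884 to 1.05. The centre value as deposited, not divided by the flank, had however a log2 change of -0.08 for Oct4/Sox2 at 128. The flank amplitude there was lower in mitosis at each concentration, from 5.82% to 2.62%, from 6.13% to 2.45% and from 6.14% to 1.04%. Without smoothing the log2 changes for Oct4/Sox2 were -0.61, -0.56 and -0.03. Around Esrrb_Book motifs it was higher, from 3.48% to 5.56%, from 3.41% to 6.42% and from 1.79% to 6.44%, but without smoothing the log2 changes at 0.5 and 128 were -0.24 and -0.05.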

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

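The tests of effect size, the tests of explanations and the counts of other splits were chosen after the results had been seen. The list tests were planned.

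The auxin effect on naive pluripotency genes differed between phases: early G1 minus late G1 had a median log2 difference of 0.20, above 0 for 20 of 22 genes (camera adjusted p 3.79e-08), and early G1 minus G2 one of 0.14 (20 of 22 genes, 0.000249). With an estimated correlation these had an adjusted p of 0.118 and 0.557. By directional fry the difference between early and late G1 had an adjusted p of 0.355, and 0.00289 with the replicate block. Primitive endoderm genes differed in early G1 minus G2 (median 0.39, 14 of 16 above 0, adjusted p 0.00011, and 0.666 with an estimated correlation) and in late G1 minus G2 (0.26, 15 of 16, adjusted p 0.0184 and 0.954). Replication-dependent histones differed in early G1 minus G2 (0.17, 63 of 71, adjusted p 0.049 and 0.935). Cytosolic ribosomal proteins differed in late G1 minus G2 (0.06, 32 of 34, adjusted p 0.0185 and 0.954). The classic Sox2 and Oct4 co-targets differed between early and late G1 with the replicate block (camera adjusted p 0.0154) and by directional fry (0.00556), but not by camera without the block (0.393, and 0.509 with an estimated correlation).

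Genes called in late G1 had a smaller auxin effect in early G1 than in G2 (fry adjusted p 0.005), and genes called in G2 a smaller one in early G1 than in late G1 (0.000924). Choice of genes in the phase of their largest effect predicts a difference near 0 between the other phases, if both share its noise equally. For genes called in late G1 the difference was -0.18, with an SD of 0.0308 over replicate numbers. Auxin-treated late G1 libraries correlated at 0.28, 0.29 and 0.29 with the same-number ones of G2 and at 0.19, 0.23 and 0.27 with early G1. Untreated ones had 0.36, 0.22 and 0.47 with G2 and 0.35, 0.29 and 0.50 with early G1. Equal sharing was therefore not shown, and the choice of genes is not set aside. A single replicate number is argued against by medians of at most -0.19 without each number. The smaller effect was not limited to genes that fell, since genes that rose also had a median of -0.19 (SD 0.053). That does not decide on RNA made before auxin was added, because RNA already present can damp a rise as well as a fall. With the replicate block, which calls other genes too, the differences shrank to -0.07 and -0.15. A candidate explanation is that early G1 cells had less time of active transcription without Sox2, which was not tested.

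For auxin in early G1, late G1 and G2, and for late G1 minus early G1, G2 minus early G1 and G2 minus late G1 without auxin, 10 splits are too few for a share under 0.05. The real counts were 17, 163, 107, 1124, 576 and 807, the highest other was 0, and 1 of the 10 splits, the real one, reached the real count. For the average, 3 of 100 drawn splits within phases called as many genes (910), so chance is excluded at 0.05 only if the libraries of a phase can be exchanged freely, which is not given where libraries of the same number correlate. Of the 10 of these splits that part every same-number pair, the real one included, the highest other called 281. Swapping 1 replicate number in all phases called 0, 0 and 0, but makes 4 splits with the real one, too few for a share under 0.05. The highest other split called 1712 genes and the next 958, which points to a structure of the samples: in each phase both put auxin-treated replicates 1 and 3 on one side and auxin-treated replicate 2 on the other. The blocked value of the average is 3939. For the differences between phases the real count of 0 (edgeR; 222, 222 and 218 at an unadjusted p under 0.05; DESeq2 1, 0 and 0) was reached by 100 of 100 splits, with highest others of 25, 1 and 469. Every split reaches a count of 0, so this says nothing about chance. The split with 469 kept the late G1 groups and swapped those of G2, so that it adds the auxin effects.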

How the results depend on the processing

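Leaving out the untreated libraries numbered 3 was chosen after seeing the data, as was the 0.2 floor for profile directions; the other alternatives were planned. The causes of the changes below were not tested, except where fewer libraries or genes enter a fit.

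At an adjusted p under 0.01 the counts were 7 (early G1), 65 (late G1), 49 (G2), 400 (average), 430 (late minus early G1), 198 (G2 minus early G1) and 366 (G2 minus late G1). DESeq2 called 50, 319, 223 and 1381 for auxin, 1 for early against late G1 and 940 for G2 minus early G1. limma on TPM with a pseudocount of 1 called 2, 9 and 8 for auxin in the 3 phases and 239, 86 and 202 between phases, and with 0.1 it called 2, 10, 6, 212, 66 and 187. Tead2, at 0.14 on counts in the average, reversed to -0.11 and -0.12. With the replicate block the counts were 255, 952, 562, 3939, 1 (early against late G1), 3487, 2360 and 2541. With the contrast's groups alone they were 6, 94, 44, 349, 161 and 360, and this was not run for the average, which uses all groups. Without the untreated libraries numbered 3 they were 9 (early G1), 594, 213 and 494 (between phases), and in the average 358 rose and 253 fell, against 416 and 494.

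Leaving out each library in turn gave 6 to 18 calls in early G1, 72 to 119 in late G1, 54 to 73 in G2, 647 to 1246 in the average, 641 to 856 for late minus early G1, 241 to 398 for G2 minus early G1 and 445 to 621 for G2 minus late G1. Of the named genes with the largest changes, 8 of 13 in early G1 lost the call in some leave-out. Gata2 in early G1 had the highest adjusted p, 0.283 without untreated replicate 3.

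With an estimated correlation, camera passed 3, 4, 2 and 4 lists for auxin, 0, 0 and 0 for differences between phases, and 2, 2 and 2 between phases. Mixed fry passed 14 (late G1), 12 (G2), 19 (average), 0, 0, 0, 18, 14 and 11, and directional fry 1 (early G1 against G2) and 0 (late G1 against G2). With the replicate block 12 lists passed in G2, 2 for early against late G1, 5 for early G1 against G2 and 11 for G2 minus early G1. In the average, mesoderm and endoderm genes (0.00559), Nodal and BMP targets (0.0128) and LIF-STAT3 targets (0.0353) passed camera with the block, against 0.185, 0.217 and 0.81 with an estimated correlation and no block. For naive genes in early G1 minus G2 directional fry gave 0.956, and 0.0293 with the block.

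The effect-size medians became -0.05 (called in early G1, reversed from 0.05) and -0.23 (late G1) at an adjusted p under 0.01, -0.07 and -0.15 (late G1, G2) with the block, and -0.25 (G2) without the untreated libraries numbered 3. Leaving out each replicate number gave 0.07 to 0.13 (none without replicate 2, where no gene was called), -0.26 to -0.19 and -0.32 to -0.27.

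The ATAC centre-to-flank ratio was lower in mitosis at 4 site classes with the flank from 200 bp, and also without smoothing. Changes of the flank amplitude that reversed (log2) were, with the flank from 200 bp, ATAC Esrrb_Book 0.11 (-1.89 in the reported setting), MNase 128 Esrrb_Lost summits -1.24, MNase-H3 128 Esrrb_Lost summits -1.16 and MNase-H3 16 EP300 0.72. Without smoothing they were ATAC Esrrb_Book 0.01, MNase 128 Esrrb_Lost Oct4/Sox2 motifs 0.14, MNase 16 EP300 0.08 and Esrrb_Lost summits 0.24, MNase-H3 Esrrb_Book -0.24 (0.5) and -0.05 (128), and MNase-H3 Esrrb_Lost -0.02 and -0.34 (128, Esrrb motif and summit) and -0.08, 0.02 and 0.02 (16, Esrrb motif, Oct4/Sox2 motif and summit). The centre value as deposited is not divided by the flank and so is another measure than the ratio. It was -0.02 for MNase 128 EP300, -0.11 for MNase-H3 128 Esrrb_Lost summits and -0.08 for MNase-H3 128 Oct4/Sox2. MNase-H3 profiles with a lower ratio in mitosis numbered 5 without smoothing, 5 within 25 bp and 0 within 100 bp, and MNase ones 5 within 100 bp, against 8. The centre value as deposited was lower in mitosis in 5 MNase-H3 and 12 MNase profiles. The planned smoothing over 11 positions and leave-outs of pooled profiles were not run.

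Of 9702 alternatives for 574 values of named genes, 8384 stayed called or stayed uncalled, 1065 lost the call, 251 gained it and 2 reversed. Direction was compared only where the reported or the alternative value passed. For the 133 values named by the size of the change, all of them called, 1872 of 2215 alternatives kept the call and 343 lost it. For lists 905 of 1080 alternatives stayed passing or stayed not passing, 76 lost the pass and 99 gained it. The block gained the call for 153 named-gene values and lost 0.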

Other observations

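The tests of explanations in this part were chosen after the results had been seen. The edgeR tests were planned.

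Cyp1a1 rose with auxin in each phase (average log2 fold change 2.72 ± 0.21, edgeR adjusted p 2.63e-07). In 3 of 3 phases the lowest count with auxin (54, 27 and 24) was above the highest without (12, 8 and 5), but all genes called in these phases met that condition, so it decides nothing about few counts. An action of auxin on the aryl hydrocarbon receptor, apart from Sox2 loss, may contribute. The other 7 tested genes of the receptor list had a median of -0.08, with Nqo1 up (0.25 ± 0.06, adjusted p 0.0148) and Ahr down (-0.54 ± 0.13, adjusted p 0.0149), which decides nothing since they went both ways. The labels list no auxin-treated line without the degron, so the effects of auxin and of Sox2 loss cannot be told apart for Cyp1a1. The same limit holds for every other gene and list in the auxin contrasts.

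The MNase signal along the flank of Oct4/Sox2 motifs had a lower amplitude in mitosis. A loss of contrast in mitotic MNase-seq digests was not seen at every site class. At Esrrb_Book motifs the amplitude was higher in mitosis at each concentration, by at least 0.21 on the log2 scale with and without smoothing. In MNase-H3 that held with the smoothed curves only. A general loss with exceptions is not decided by this. Of 21 MNase-seq profiles 14 had an amplitude lower by at least 0.2, and the pooled profiles carry no error. The smoothing may contribute to the size of the fall: in the unsmoothed profiles at Oct4/Sox2 motifs the log2 change was -0.61 to -0.03, so it stays open. Sox2 and Oct4 binding was not analysed here, and no biological explanation was tested.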
